A study of Homo sapiens with 6 samples.

How the data were processed

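RNA sequencing libraries of A498 cells were compared between a control for the knockdown of PTPRZ1 (PTPRZ_nc) and the knockdown (PTPRZ_Si), with 3 libraries in each group. Per the labels' protocols, total RNA was extracted with a Qiagen kit and libraries were made with a directional Illumina kit of NEBNext. The groups and replicate numbers were taken from the labels. The labels name a plasmid as the means of knockdown for the control group and siRNA for the knockdown group, and the sequences of either are not given in the sources used here.

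The authors deposited counts, whole numbers of read pairs per gene that were not normalized. Per the file headers, they were made with featureCounts version 2.0.1 in paired mode over exons grouped by gene, with the Ensembl annotation of GRCh38, release 107, from alignments whose names contain hisat. The aligner's version is not given in the sources used here, and hg38 is the build per the submitters' processing notes. The command in the file headers sets no strand option, so reads from overlapping genes on opposite strands were not told apart although the library kit keeps strand. It sets no option to count read pairs with several placements or several genes either, and by the program's default those are left out, so a gene with near-identical copies in the reference is under-counted or listed at 0. Whether the reference held alternate contigs is not given in the sources used here.

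Some sets of genes have few or no counts, and why was not tested. All 37 genes of the mitochondrial genome and all 54 genes on unplaced scaffolds are listed at 0, while the nuclear pseudogene MTATP6P1 has 155864 counts over the 6 libraries. On chromosome 6 between 29 and 34 Mb, 172 of 182 protein-coding genes (94.5%) have under 100 counts over the 6 libraries, against 344 of 857 (40.1%) on the rest of the chromosome (2-sided Fisher's exact test, p = 1.37e-46), a region chosen after the counts were seen. Genes that most cells use are among those with few counts, such as RPS18 with 11 and TUBB with 41, and PSMB3 on chromosome 17 with 2. A gene listed at or near 0 in these data is therefore not shown to be silent.

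The table holds 61860 genes. Symbols came from a gene name table for 42054 of them and from GENCODE release 29 (GRCh38) for another 16371, and 3435 had no symbol. Coordinates are those of GENCODE 29. Total counts per library ran from 13726908 to 21469746, 23038 to 25553 genes had a count, the 10 most counted genes held 3.29% to 3.46% of the counts, and TMM factors ran from 0.9936 to 1.009. Limits for a count of 0 were set at 3 counts.

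Genes were tested with edgeR 4.0.16 in R 4.3.3: genes with low counts were removed with filterByExpr, which left 15476 genes with 99.82% of the counts, libraries were scaled by TMM, and the groups were compared with glmQLFit and glmQLFTest, 2-sided, with Benjamini-Hochberg adjustment over the tested genes. A gene was called at an adjusted p of at most 0.05. The estimated coefficient of variation beyond counting was 5.53%, a low value. CPM values are scaled by TMM. Pairs of libraries within a group differed by more than sampling noise (chi-square per degree of freedom of 2.19 to 6.23), so none was taken for a second copy of another. This does not show that they came from separate cultures. On simulated counts with the means and sizes of these libraries, the same comparison over 15247 genes recovered 40% of genes changed 1.25-fold, 76% at 1.5-fold, 84% at 2-fold and 98% at 4-fold, 50 genes each, with 13 false calls among 15047 unchanged genes. The changed genes were drawn from those with a mean of at least 1 CPM and were far fewer than the genes called here. These shares therefore do not give the power of the real comparison.

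A total of 39 gene lists were fixed before the data were examined, and the 34 with at least 5 tested members were compared with all other genes by camera of limma 3.58.1 with a preset correlation of 0.01, adjusted over the 34 lists. With the correlation estimated from these libraries, 7 of the 13 calls hold: NRF2 targets, fatty acid synthesis, interferon-stimulated genes, G2/M, extracellular matrix, YAP and HIF. Mitochondrially encoded mRNAs could not be tested, with 0 of 13 members counted. In a simulation with the cholesterol list shifted by 0.3 on the log2 scale, camera called that list and 1 other of the 34.

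The rule for the genes named in the text was also fixed before the data were examined. It takes PTPRZ1, RNF26 and CBX7 always; then, among called genes with a symbol, a mean of at least 5 CPM and no overlap between groups, the 10 with the largest and the 10 with the smallest log2 fold change; then the 4 members with the smallest p of each list that passed and at most 2 of each other list; and the 5 genes with the smallest p in each direction. Some genes that meet the rule are not reported here. Members named because they moved against their list or did not pass were chosen after their values were seen, as were the genes named for their low counts and those named with words of their 3' untranslated regions.

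Alternatives tried were other scalings (DESeq2 size factors, upper quartile, library totals), limma-voom, DESeq2 1.42.0, other filters on low counts, a fold threshold of 1.2 in glmTreat, an adjusted p of at most 0.01, the replicate number as a block, list tests with fry, leaving out each library in turn, and, chosen after the data were seen, leaving out 2 libraries and removing a trend with transcript length and GC content. To look for small RNA seed matches, the fold changes of 10416 genes with an annotated 3' untranslated region of at least 50 bases and a mean of at least 5 CPM were regressed on the presence of each of 16190 words of 7 bases, given the region's length and GC content and the expression level. The z of each word was divided by the inflation over all words (1.256). In 3 simulated scans with a shift of -0.1, -0.2 or -0.3 implanted for 1 word, that word ranked 1 each time. The words were carried by 918, 504 and 1357 genes, all of them shifted, on fold changes permuted over genes. These scans therefore do not give the power for rarer words or for shifts in only some of the carriers.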

Results

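RNA of A498, a human cell line from a clear cell kidney carcinoma, was sequenced to compare cells with a knockdown of PTPRZ1 with control cells. PTPRZ1 encodes a receptor protein tyrosine phosphatase. The series title names the question: the enzyme and RNF26, an E3 ubiquitin ligase of the endoplasmic reticulum, are set against the response of clear cell kidney cancer to kinase inhibitors and to blockade of the immune checkpoint receptor PD-1. The 6 libraries form 2 groups of 3, the control (PTPRZ_nc) and the knockdown (PTPRZ_Si). Total counts in genes were 17083498, 13726908 and 18609477 in control replicates 1, 2 and 3, and 14407846, 21003207 and 21469746 in knockdown replicates 1, 2 and 3. The labels do not say whether the replicates came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

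PTPRZ1 (ENSG00000106278, GRCh38 chromosome 7 from 121873089 to 122062036, plus strand) had 0 counts in each of the 6 libraries. With 3 counts as the limit that a count of 0 allows, its counted level was at most 0.0607 CPM (counts scaled to library size) over the 3 controls together, which hold 49419883 counts. Single libraries allow 0.14 to 0.219 CPM, and all of these limits cover counting error only. AASS, the nearest protein-coding gene at 13.6 kb, had 1714 counts over the 6 libraries, and FAM3C, on the other side at 477 kb, had 18744. A fall of PTPRZ1 in the knockdown was therefore not detectable in these counts, no fold change was computed for it, and the knockdown could not be checked against the labels by its target. All directions below rest on the group labels.

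Knockdown and control libraries differed in 4243 of 15476 tested genes at an adjusted p of at most 0.05 in edgeR's quasi-likelihood test, 2164 higher and 2079 lower in the knockdown. RNF26 (chromosome 11 from 119334527 to 119337313) fell from 48.95 ± 0.94 to 41.1 ± 3.55 CPM (SD, n = 3 each), a log2 fold change of -0.25 (SE 0.07, edgeR adjusted p = 0.0128). CBX7 (chromosome 22 from 39120167 to 39152674), a Polycomb protein that reads methylated histone H3, fell from 22.2 ± 1.53 to 18.24 ± 0.651 CPM (log2 fold change -0.28, SE 0.0855, edgeR adjusted p = 0.0225). Changes were small for most genes: the median called gene differed 1.26-fold, 3512 called genes differed by less than 1.5-fold and 224 by 2-fold or more. The groups did not overlap for 4110 of the called genes. The groups also did not overlap for 40.8% of all tested genes against 10% by chance. Without knockdown replicate 1 or 2, RNF26 no longer passed (edgeR adjusted p = 0.061 and 0.0697), and CBX7 did not pass without control replicate 2, knockdown replicate 1 or knockdown replicate 3 (edgeR adjusted p = 0.0655, 0.077 and 0.0642). Nor did CBX7 pass without both control 2 and knockdown 2 (edgeR adjusted p = 0.0749).

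EGR1, an immediate early transcription factor, fell from 12.71 ± 1.43 to 0.822 ± 0.13 CPM (SD, n = 3 each, edgeR adjusted p = 2.43e-10), 15.52-fold lower and the largest fall among the genes that met the naming rule. NT5E, the ecto-enzyme that makes adenosine from AMP, fell from 41.87 ± 0.323 to 16.77 ± 0.858 CPM, and F3, tissue factor, from 20.48 ± 0.585 to 8.997 ± 0.239 CPM. INHBA, a subunit of activin (log2 fold change -1.19, SE 0.106), the cation transporter SLC22A4 (-1.18, SE 0.115) and the SNARE protein STX12 (-1.12, SE 0.0918) fell by similar amounts. Falls with some of the smallest p were those of the tropomyosin TPM4 (-0.94, SE 0.0388), IGFBP3, which binds insulin-like growth factors (-0.68, SE 0.0293), APOL1 (-0.77, SE 0.0331) and the long noncoding RNA AC079466.1 (-0.91, SE 0.0399).

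EFCAB13 had the largest rise among the genes that met the naming rule, from 10.25 ± 0.512 to 33.53 ± 2.95 CPM (SD, n = 3 each), a log2 fold change of 1.70 (SE 0.0928, edgeR adjusted p = 7.63e-10). GDA, guanine deaminase, rose from 53.48 ± 0.613 to 124.1 ± 2.47 CPM, and CCN3, a matricellular protein, from 28.75 ± 2.53 to 70.91 ± 0.949 CPM. LGR4, a receptor for R-spondins, rose from 82.55 ± 1.88 to 179.4 ± 1.49 CPM and NCS1, a neuronal calcium sensor, whose 3' untranslated region carries AACACGAA, from 170.3 ± 5.08 to 352.8 ± 1.44 CPM. SPP1, osteopontin, rose from 1051 ± 30.2 to 1778 ± 25.6 CPM and the unconventional myosin MYO10 from 336.8 ± 4.21 to 614.6 ± 16.1 CPM. Other large rises were CDS1, an enzyme of phosphatidylinositol synthesis (log2 fold change 1.33, SE 0.0972), AFF2 (1.29, SE 0.142), the ephrin receptor EPHA4 (1.26, SE 0.0923) and C5AR1, the receptor of complement C5a (1.21, SE 0.156).

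Several of the largest values rest on few or uneven counts. ITPK1 (log2 fold change 1.54, SE 0.397) had 849 counts in knockdown replicate 3 and 149 and 200 in the other knockdown libraries, and did not pass with limma-voom (adjusted p = 0.0503) or DESeq2 (adjusted p = 0.0904). YTHDC1 (1.63, SE 0.341) had 136, 29 and 47 counts in the controls and 255, 290 and 177 in the knockdown. VAMP7 (-3.27, SE 0.549), which has a second copy in the part shared by the sex chromosomes, had 34, 207 and 384 counts in the controls and 20, 26 and 27 in the knockdown. The noncoding RNA FP236383.3 (-1.74, SE 0.325) had 316, 104 and 560 counts in the controls and 70, 91 and 162 in the knockdown. AL157935.1 (1.18, SE 0.0773) is annotated as antisense to another gene, and reads of the 2 strands were not told apart in the counting.

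**Figure D1:**
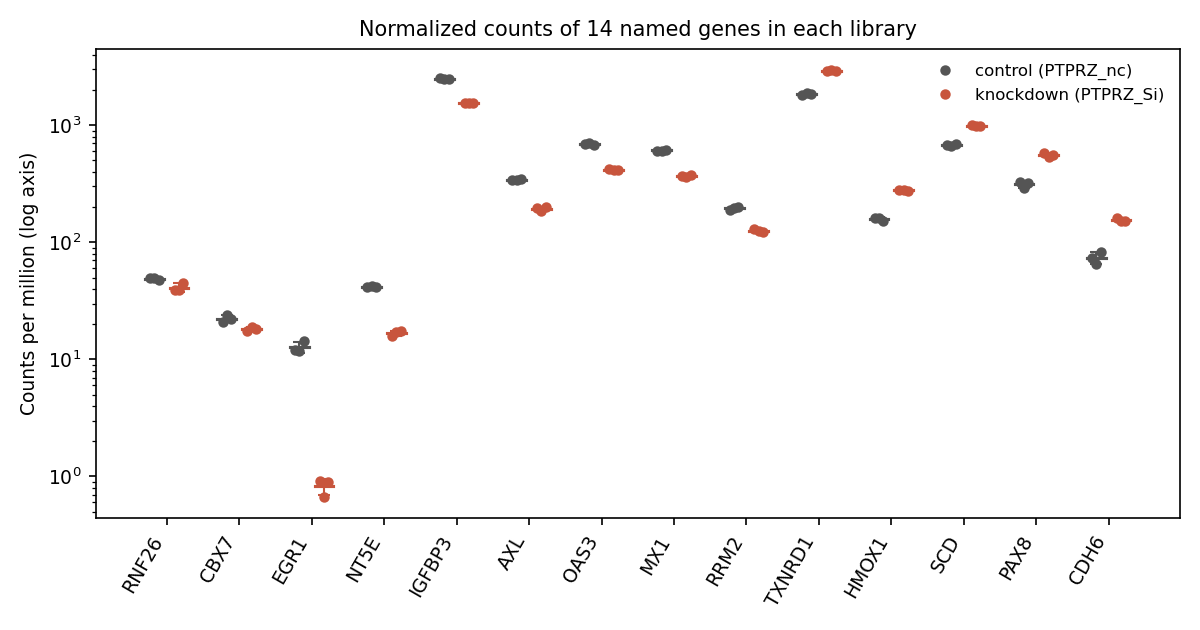
CPM of 14 named genes on a log axis, with gene symbols on the horizontal axis; each point is 1 library, horizontal bars are group means and whiskers SD (n = 3 per group), grey for the control and red for the knockdown. IGFBP3 sits near 2494 CPM in the control and 1553 CPM in the knockdown, and TXNRD1 near 1845 and 2920 CPM.

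Targets of NRF2, the transcription factor of the response to oxidants, were higher in the knockdown. Of 23 tested members 18 rose, 0 fell and 5 did not pass, with the same counts adjusted over the list alone, and the list's median log2 fold change was 0.31 (camera adjusted p = 5.76e-19, and adjusted p = 0.0422 with an estimated correlation). TXNRD1, thioredoxin reductase, rose from 1845 ± 43.9 to 2920 ± 37.3 CPM (SD, n = 3 each). HMOX1, heme oxygenase, rose from 159.1 ± 4.79 to 277.9 ± 1.88 CPM and the conjugate exporter ABCC2 from 172.6 ± 3.29 to 255.1 ± 4.69 CPM. AKR1C1, an aldo-keto reductase, rose from 971.2 ± 16.6 to 1341 ± 28.2 CPM. It has close paralogs, and reads placed in several of them could be left out of the counting. The members that did not pass were GCLC (0.07), TXN (0.11), SRXN1 (0.23), ME1 (-0.07) and FTH1 (0.17). For FTH1, control replicate 2 stood apart, with 1467 CPM against 2078 and 2086 CPM in the other controls.

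Genes of fatty acid synthesis and lipid storage were also higher. Of 19 tested members 12 rose, 3 fell and 4 did not pass, against 12 higher and 4 lower adjusted over the list alone (median log2 fold change 0.28, camera adjusted p = 3.5e-06, and adjusted p = 0.0476 with an estimated correlation). SCD, the desaturase that makes monounsaturated fatty acids, rose from 683.7 ± 13.9 to 984.8 ± 11.9 CPM (SD, n = 3 each), and ACLY, which makes cytosolic acetyl-CoA, from 472.5 ± 15.5 to 646.7 ± 7.67 CPM. The elongase ELOVL6 rose from 42.56 ± 3.14 to 76.4 ± 1.86 CPM and the acyl-CoA synthetase ACSL1 from 204.4 ± 6.74 to 299.9 ± 3.63 CPM. The 3 members that fell were the lipid droplet proteins PLIN2 (-0.26) and PLIN3 (-0.25) and the acyltransferase GPAM (-0.37).

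Renal tubule lineage genes were higher as a list. Of 14 tested members 6 rose, 2 fell and 6 did not pass, against 7 higher and 2 lower adjusted over the list alone (median log2 fold change 0.37, camera adjusted p = 0.00206, but adjusted p = 0.141 with an estimated correlation). Without knockdown replicate 2 the list had 3 higher and 1 lower, and without control 2 and knockdown 2 it had 3 higher and 2 lower. PAX8, a transcription factor of kidney development, rose from 313.2 ± 21.3 to 556 ± 22.4 CPM (SD, n = 3 each) and the cadherin CDH6 from 73.98 ± 8.13 to 154.7 ± 4.68 CPM. The 2 members that fell were the homeobox genes IRX3 (-0.43, SE 0.0884) and LHX1 (-1.05, SE 0.317). Wnt and beta-catenin targets gave 6 higher, 0 lower and 8 not passed of 14, with 7 higher and 0 lower adjusted over the list alone (median 0.29, camera adjusted p = 0.0164, but adjusted p = 0.141 with an estimated correlation). Without control replicate 2 the Wnt list had 7 higher and 2 lower, and without control 2 and knockdown 2 it had 6 higher and 2 lower. Leaving out any other single library gave 4 or 5 higher and 0 lower. ZNRF3, a ligase that removes Wnt receptors, rose from 31.02 ± 1.39 to 53.01 ± 5.83 CPM, the cyclin CCND1 from 412.5 ± 6.05 to 489.4 ± 11 CPM and the transcription factor TCF7 from 59.35 ± 4.91 to 74.45 ± 3.32 CPM. SP8, at 1.891 ± 0.359 and 3.354 ± 0.567 CPM, did not pass without control replicate 3, knockdown replicate 1 or knockdown replicate 2 (edgeR adjusted p = 0.0736, 0.0527 and 0.0783), and the Wnt list did not pass when only genes with a mean of at least 5 CPM were tested (camera adjusted p = 0.0786).

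Interferon-stimulated genes were lower in the knockdown libraries. Like every difference between these groups, this cannot be separated from the plasmid and siRNA that the labels name. Of 28 tested members 19 fell, 0 rose and 9 did not pass, with the same counts adjusted over the list alone (median log2 fold change -0.39, camera adjusted p = 1.21e-16, and adjusted p = 0.0422 with an estimated correlation). The antiviral genes OAS3 and OAS2, which make 2'-5' oligoadenylates, fell from 691.4 ± 12 to 417.4 ± 6.31 CPM and from 447.9 ± 6.73 to 265 ± 5.58 CPM (SD, n = 3 each). MX1, an antiviral GTPase, fell from 610.2 ± 4.2 to 369 ± 7.01 CPM and IFIT1 from 116.9 ± 0.805 to 76.9 ± 3.28 CPM. Among the members that did not pass were the transcription factors IRF7 (-0.15) and IRF9 (-0.25). Of 13 tested components of the STING pathway, which senses cytosolic DNA, IFI16 fell (log2 fold change -0.28, SE 0.0538), USP13 rose (0.36, SE 0.0728) and 11 did not pass, STING1 among them at -0.03, with the same counts adjusted over the list alone (median -0.03, camera adjusted p = 0.674).

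Genes of antigen presentation by MHC class I were lower in the knockdown, although only 11 of 18 listed members had enough counts to be tested. Of these 11 6 fell, 0 rose and 5 did not pass, with the same counts adjusted over the list alone (median log2 fold change -0.22, camera adjusted p = 0.000937, but adjusted p = 0.0782 with an estimated correlation). B2M, the light chain of class I molecules, fell from 729.2 ± 25.3 to 607.9 ± 10.7 CPM (SD, n = 3 each), the chaperone CALR from 840.6 ± 32.4 to 697.9 ± 3.13 CPM and the peptidase ERAP1 from 100.5 ± 2.73 to 77.66 ± 3.45 CPM. HLA-B had 402, 219 and 250 counts in the controls and 99, 163 and 139 in the knockdown (log2 fold change -1.31, SE 0.171), while HLA-C (0.32) did not pass. The class I heavy chains differ between alleles and resemble one another, so their counts are uncertain. The untested members include TAP1 with 3 counts over the 6 libraries, PSMB8 with 2, PSMB9 with 3, TAPBP with 16 and HLA-E with 43. They lie on chromosome 6 between 29 and 34 Mb, where 172 of 182 protein-coding genes had under 100 counts, the ribosomal protein gene RPS18 among them with 11, against 344 of 857 on the rest of that chromosome.

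Targets of NF-kB and TNF were lower as a list, with members in both directions. Of 23 tested members 8 fell, 4 rose and 11 did not pass, against 10 lower and 5 higher adjusted over the list alone (median log2 fold change -0.08, camera adjusted p = 0.0154, but adjusted p = 0.123 with an estimated correlation). SOD2, mitochondrial superoxide dismutase, fell from 624.5 ± 26.1 to 404.6 ± 4.59 CPM (SD, n = 3 each), the adaptor TRAF1 from 60.21 ± 2.3 to 33.51 ± 0.668 CPM and the chemokine CXCL8 from 17.76 ± 0.723 to 9.931 ± 0.813 CPM. The 4 that rose were TNIP1 (0.34, SE 0.0463) and the cytokines IL6 (0.40), CCL2 (0.30) and IL1B (1.16). For immune checkpoint ligands, 4 of 13 tested members fell, 1 rose and 8 did not pass, against 5 lower and 2 higher adjusted over the list alone (median -0.06, camera adjusted p = 0.302). The checkpoint list had 2 higher without control replicate 1 and 3 lower without knockdown replicate 1 or 2. CD276 rose from 226.6 ± 0.563 to 333.8 ± 6.72 CPM, and CD274, the PD-1 ligand, did not pass (log2 fold change -0.11). The 4 members that fell were NT5E, PVR (-0.20), NECTIN2 (-0.17) and CD47 (-0.22).

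Cell cycle genes were lower in the knockdown. Of 26 genes of G2/M and mitosis 21 fell, 1 rose and 4 did not pass, against 22 lower and 1 higher adjusted over the list alone (median log2 fold change -0.26, camera adjusted p = 9.07e-08, and adjusted p = 0.0422 with an estimated correlation). ANLN, a scaffold of the contractile ring, fell from 302.9 ± 16.8 to 229.6 ± 3.88 CPM (SD, n = 3 each), the survivin gene BIRC5 from 149 ± 11 to 109.7 ± 2.93 CPM, the cyclin CCNA2 from 99.65 ± 6.22 to 72.42 ± 2.84 CPM and the kinase AURKB from 48.98 ± 1.61 to 35.87 ± 1.35 CPM. The 1 member that rose was MKI67 (0.23), whose 3' untranslated region carries AACACGAA. Of 26 genes of G1/S and DNA replication 16 fell, 1 rose and 9 did not pass, with the same counts adjusted over the list alone (median -0.23, camera adjusted p = 4.71e-07, but adjusted p = 0.118 with an estimated correlation). The subunits of ribonucleotide reductase RRM2 and RRM1 fell from 195.6 ± 5.97 to 126 ± 3.3 CPM and from 142 ± 8.65 to 94.51 ± 3.61 CPM, and the replication genes MCM4 (-0.32, SE 0.0432) and CDC45 (-0.42, SE 0.0689) also fell. CCNE1, a cyclin of entry into S phase, rose (0.30).

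Genes of the extracellular matrix and of mesenchymal cells were lower in the knockdown. Of 24 tested members 10 fell, 2 rose and 12 did not pass, against 10 lower and 3 higher adjusted over the list alone (median log2 fold change -0.12, camera adjusted p = 1.09e-07, and adjusted p = 0.0476 with an estimated correlation). The fibronectin receptor subunit ITGA5 fell from 700.7 ± 28 to 438.5 ± 11.2 CPM and TGFBI, a matrix protein, from 1224 ± 14.7 to 835.3 ± 13.5 CPM (SD, n = 3 each). SPARC, a matrix glycoprotein, went the other way, from 1301 ± 17.2 to 1977 ± 26 CPM, as did the transcription factor ZEB1 (0.25). FN1, fibronectin itself, did not pass (-0.04). Of 21 targets of YAP and TEAD, the transcription factors of the Hippo pathway, 8 fell, 7 rose and 6 did not pass, against 8 lower and 8 higher adjusted over the list alone (median -0.11, camera adjusted p = 5.65e-05, and adjusted p = 0.0476 with an estimated correlation). The members with the smallest p all fell: IGFBP3 from 2494 ± 30.2 to 1553 ± 15.7 CPM, the receptor kinase AXL from 343 ± 1.93 to 194.5 ± 7.39 CPM, CCN1 from 197.1 ± 5.05 to 111.8 ± 1.13 CPM and NT5E.

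Targets of the hypoxia-inducible factors (HIF) were lower as a list. Of 26 tested members 10 fell, 5 rose and 11 did not pass, against 11 lower and 5 higher adjusted over the list alone (median log2 fold change -0.15, camera adjusted p = 0.000147, and adjusted p = 0.0476 with an estimated correlation). ANGPTL4, an inhibitor of lipoprotein lipase, fell from 225.5 ± 12.4 to 107.7 ± 3.66 CPM (SD, n = 3 each), the collagen hydroxylase P4HA2 from 178.7 ± 5.54 to 93.47 ± 6.34 CPM, EGLN3 from 546.4 ± 21.2 to 390.5 ± 4.19 CPM and the peptide hormone gene ADM from 115.7 ± 4.91 to 75.9 ± 1.66 CPM. The 5 that rose were BNIP3 (0.29), ENO1 (0.25), P4HA1 (0.39), which carries AACACGAA in its 3' untranslated region, HK2 (0.31) and MXI1 (0.53). Of 19 ER chaperones and genes of the unfolded protein response 9 fell, 2 rose and 8 did not pass, against 9 lower and 3 higher adjusted over the list alone (median -0.14, camera adjusted p = 0.0418, but adjusted p = 0.259 with an estimated correlation). HSP90B1 fell from 847.9 ± 16.2 to 705.2 ± 11.3 CPM, PDIA6 from 301.6 ± 18.6 to 252.6 ± 2.16 CPM and the stress sensor ATF6 from 90.18 ± 4.23 to 65.85 ± 0.411 CPM, while HERPUD1 rose from 138 ± 1.25 to 174.9 ± 7.35 CPM. The ER list did not pass without control replicate 2 or knockdown replicate 3 (camera adjusted p = 0.0559 and 0.0511), without control 2 and knockdown 2 (0.0587) or with a length and GC trend removed (0.0549). It had 5 lower members in place of 9 without knockdown replicate 1. Nor did it pass among genes with a mean of at least 5 CPM (camera adjusted p = 0.0936).

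**Figure D2:**
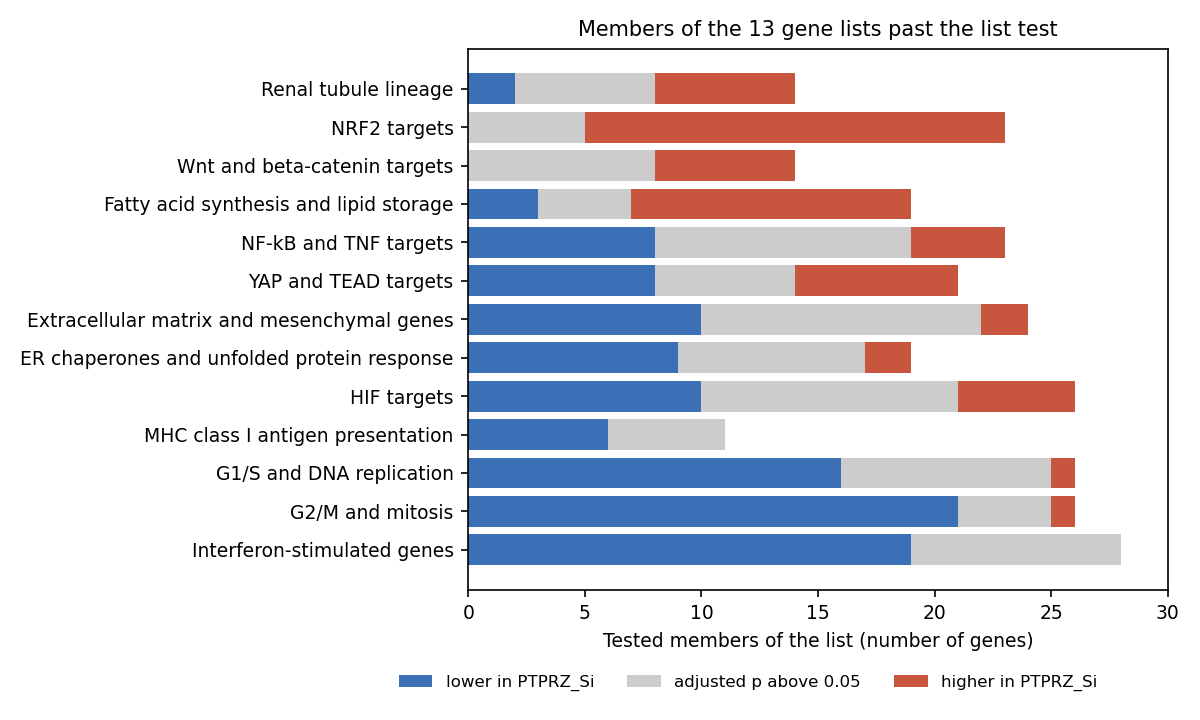
Number of tested genes (horizontal axis) in each of the 13 gene lists that passed the list test (vertical axis); blue bars count members lower in the knockdown, red bars members higher, and grey bars members with an adjusted p above 0.05. NRF2 targets hold 18 higher and 0 lower members, and interferon-stimulated genes 0 higher and 19 lower.

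The targets of kinase inhibitors, receptors and their ligands, did not pass as a list (camera adjusted p = 0.0503), a call that changes with the processing. The list passed with scaling by library totals and without control replicate 1, control replicate 3 or knockdown replicate 2 (camera adjusted p = 0.0412, 0.0438, 0.0469 and 0.0346). It also passed without control 2 and knockdown 2 (0.0419) and with a length and GC trend removed (0.0255). Of 14 tested members 6 fell, 5 rose and 3 did not pass, with the same counts adjusted over the list alone. Without control replicate 1, control replicate 3, knockdown replicate 1 or knockdown replicate 3 only 2, 3, 1 and 3 rose. The median log2 fold change (0.0018) lay on the other side of 0 from the mean (-0.16) and the test. AXL fell 1.76-fold, and VEGFA, the vascular growth factor, fell from 635 ± 20.7 to 493.5 ± 5.84 CPM (SD, n = 3 each). Genes for ligands, partners and substrates of PTPRZ1 gave 7 higher, 2 lower and 12 not passed of 21, with the same counts adjusted over the list alone (median 0.06, camera adjusted p = 0.0503). As a list they passed without control replicate 1 or knockdown replicate 2 (0.0496 and 0.0346) and without control 2 and knockdown 2 (0.0339). The kinase SRC rose from 537.5 ± 6.64 to 709.2 ± 15.9 CPM and the scaffold GIT1 from 66.91 ± 1.33 to 96.3 ± 0.555 CPM, while the ligands PTN (-0.26) and MDK (-0.41) did not pass. Of 15 other receptor tyrosine phosphatases 4 rose, 2 fell and 9 did not pass, against 4 higher and 3 lower adjusted over the list alone (median 0.03, camera adjusted p = 0.796). PTPRS rose (0.39, SE 0.0404) and PTPRF fell (-0.29, SE 0.0411). Of 16 Polycomb genes 3 rose, 4 fell and 9 did not pass, against 3 higher and 5 lower adjusted over the list alone (median 0.0096, mean -0.0036, test downward, camera adjusted p = 0.998). Only 1 rose without control replicate 1 or 3 or knockdown replicate 2 or 3, and 2 fell without knockdown replicate 1. CBX6 rose (0.47, SE 0.0412), and KDM2B fell (-0.33, SE 0.0614).

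Most markers of other cell types were near 0 CPM. Only 2 of 20 haematopoietic, 3 of 14 endothelial, 2 of 11 keratinocyte and 4 of 12 neural markers had enough counts to be tested, too few for a list test. Of these 11 genes MAP2 alone passed (log2 fold change 0.44). Of 5 tested markers of fibroblasts and pericytes COL1A1 fell from 35.08 ± 5.43 to 22.02 ± 1.23 CPM (SD, n = 3 each) and 4 did not pass, against 3 lower adjusted over the list alone (median -0.55, camera adjusted p = 0.127). The number of lower markers was 2 without control replicate 1, 3 without control replicate 2 and 2 without control 2 and knockdown 2. It stayed at 1 with any other single library left out. ACTA2, at 4.452 ± 0.78 and 3.059 ± 0.433 CPM, was at the threshold (log2 fold change -0.56, edgeR adjusted p = 0.0503). Reference genes often used to scale measurements gave 4 higher, 9 lower and 3 not passed of 16, with the same counts adjusted over the list alone (median -0.14, camera adjusted p = 0.0503). The reference list passed with scaling by library totals (0.0412), without control replicate 1, control replicate 2 or knockdown replicate 2 (0.0344, 0.0324 and 0.0346) and without control 2 and knockdown 2 (0.0202), and had 1, 2 and 1 higher without knockdown replicate 1, 2 or 3 and 5 lower without the last. ACTB fell from 4110 ± 79.1 to 3321 ± 26.6 CPM and POLR2A from 456.2 ± 21.6 to 334 ± 14.7 CPM. Of 28 cytosolic ribosomal protein genes 4 rose, 0 fell and 24 did not pass, against 2 higher adjusted over the list alone (median 0.06, camera adjusted p = 0.219), and 2, 2 and 1 rose without control replicate 3, knockdown replicate 1 or knockdown replicate 2.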

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

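Leaving out both control 2 and knockdown 2 and removing a length and GC trend were chosen after the data were seen. Over all alternatives, 0 genes called both there and in the main comparison changed direction, and genes that lost their call were not counted in this. The count of 4243 called genes was 3753 to 4404 under other scalings, filters and tools and with the trend removed, and 3182 (without knockdown replicate 1) to 4425 (without control replicate 2) with single libraries left out. Without control 2 and knockdown 2 it was 4219, with NRF2 targets at 19 higher and 0 lower of 23 and interferon-stimulated genes at 18 lower and 2 higher of 28, but the renal tubule list at 3 higher and 2 lower of 14. The glmTreat test for changes beyond 1.2-fold called 896 genes, 521 higher and 375 lower, since most calls are small, and higher genes made up 58.15% of its calls against 51% in the main comparison. At an adjusted p of at most 0.01, 2655 genes passed, 1383 higher and 1272 lower, 118 of them 2-fold or more. Among genes with a mean of at least 5 CPM, 56 changed 2-fold or more in place of 224, so low counts hold most of the large changes. The RNF26 log2 fold change ran from -0.33 (without knockdown replicate 3) to -0.21 (without knockdown replicate 2) with single libraries left out. It was -0.20 without control 2 and knockdown 2 (edgeR adjusted p = 0.0465). In glmTreat it was -0.25 and did not pass (adjusted p = 0.964). At the threshold of 0.01 RNF26 did not pass either, with an edgeR adjusted p of 0.0128 in the main comparison. Over the other alternatives without a left-out library its adjusted p ran from 0.00298 to 0.0148. PTPRZ1 has 0 counts throughout, so its planned fold change has no value under any alternative. Of the 115 called named genes, 31 did not pass in glmTreat and 8 did not pass in at least 1 other alternative, and ACTA2 passed in 5. The list test called 13 lists, 7 with an estimated correlation, and 11 to 17 under the other alternatives of camera. As tests that do not compare a list with other genes, fry called 22 lists moving 1 way on balance and 32 with changes in either direction. A fit with the replicate block called 4101 genes, 3998 of them among the 4243. The deviations of same-numbered libraries correlated at 0.027, 0.033 and 0.023, and those of libraries with different numbers at -0.023 to -0.005. Each of the 6 thus correlated best with its own number, a hint from the data and not the design. The correlations are small and do not settle whether same-numbered libraries share more than a number. The block ended the call of 1 named gene, H4C8 (adjusted p = 0.0505), and brought 1 more list, apoptosis regulators, past the threshold (camera adjusted p = 0.0476). If reads of PTPRZ1 were counted at all, depth limits it to at most 0.0607 CPM in the controls.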

Other observations

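Immediate early genes and other outputs of MAPK signalling had members in both directions. Of 21 tested members 7 were higher, 5 lower and 9 did not pass in the knockdown, against 9 higher and 5 lower adjusted over the list alone, and 4 were higher without knockdown replicate 3; the median log2 fold change was 0.14 and the mean -0.10, and the test pointed upward (camera adjusted p = 0.705). EGR1 (-3.96, SE 0.192), FOS (-0.82, SE 0.167), FOSL1 (-0.41), IER2 (-0.45) and EPHA2 (-0.23) fell, and DUSP5 (0.32), SPRY4 (0.31), SPRED1 (0.39), ETV4 (0.28), ETV5 (0.16), CCND1 and EPHA4 rose. The members that did not pass were JUNB (0.10), FOSB (-0.20), MYC (-0.10), PHLDA1 (-0.05), DUSP4 (0.21), DUSP6 (0.02), SPRY1 (0.41), SPRY2 (0.31) and SPRED2 (0.14). Epithelial junction genes also had members in both directions, with 7 higher, 5 lower and 6 not passed of 18 and the same counts adjusted over the list alone (median -0.21, camera adjusted p = 0.6). The junction genes F11R (-0.65, SE 0.0665) and CLDN1 (-0.40, SE 0.0447) fell, and CLDN2 (0.77, SE 0.175) and KRT19 (0.76, SE 0.205) rose.

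Metabolic and stress lists that did not pass held single called genes, and several counts change when single libraries are left out. Without knockdown replicate 1, ATF4 targets and glycolysis genes had 3 higher, apoptosis regulators 1 higher and oxidative phosphorylation genes 1 lower; without knockdown replicate 2, cholesterol genes had 4 higher; without knockdown replicate 3, apoptosis regulators had 1 higher and oxidative phosphorylation genes 0 lower, as without control replicate 3. Of 21 cholesterol synthesis genes 7 rose, 2 fell and 12 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.0836), among them HMGCS1, up from 70.82 ± 2.34 to 112.1 ± 4.17 CPM (SD, n = 3 each). Of 19 glycolysis genes 6 rose, 3 fell and 10 did not pass, against 6 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.983), with falls of the glucose transporter SLC2A1 (-0.42, SE 0.0396) and ENO2 (-0.64, SE 0.0784). Of 27 nuclear genes of oxidative phosphorylation 3 rose, 3 fell and 21 did not pass, against 3 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.761), and UQCRC2 rose from 89.54 ± 1.47 to 144 ± 4.32 CPM. Heat shock genes gave 6 higher, 1 lower and 7 not passed of 14 (3 higher without knockdown replicate 1), with the same counts adjusted over the list alone (camera adjusted p = 0.0554), with STIP1 (0.46, SE 0.0454) and BAG3 (0.34, SE 0.0473) higher. The heat shock list passed without control replicate 2 (0.0324), without control 2 and knockdown 2 (0.0339) and with the length and GC trend removed (0.0388). Lysosome and autophagy genes gave 8 higher, 4 lower and 10 not passed of 22, against 9 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.173), with GPNMB higher (0.55, SE 0.0569) and CTSD lower (-0.27, SE 0.0339). ATF4 targets gave 6 higher, 8 lower and 10 not passed of 24, against 7 higher and 8 lower adjusted over the list alone (median 0.04, mean 0.01, test downward, camera adjusted p = 0.844), with CHAC1 (0.39, SE 0.0519) and SLC7A5 (0.26, SE 0.0348) higher. Of 24 p53 targets 6 rose, 8 fell and 10 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.684), CCNG1 rising (0.37, SE 0.0447) and GADD45A falling (-0.59, SE 0.0617). Of 20 apoptosis regulators 3 rose, 6 fell and 11 did not pass, against 3 higher and 9 lower adjusted over the list alone (camera adjusted p = 0.0503), with BIRC2 (-0.51, SE 0.056) falling. The apoptosis list passed with scaling by library totals and without control replicate 1 or knockdown replicate 2 (camera adjusted p = 0.0441, 0.0278 and 0.0346). RNA interference genes gave 4 higher, 2 lower and 7 not passed of 13, with the same counts adjusted over the list alone (median -0.0033, mean 0.07, test upward, camera adjusted p = 0.6), and AGO2, the slicing Argonaute, rose from 72.16 ± 6.72 to 106.2 ± 6.56 CPM. Of 7 tested histone genes H1-2 rose (0.42, SE 0.117), H4C8 fell (-0.57, SE 0.203) and 5 did not pass, with the same counts adjusted over the list alone (median -0.0031, mean -0.02, test upward, camera adjusted p = 0.983). H1-2 did not pass without control replicate 1, knockdown replicate 2 or knockdown replicate 3 (edgeR adjusted p = 0.0624, 0.0788 and 0.0529). H4C8 did not pass without control replicate 2, control replicate 3, knockdown replicate 2 or knockdown replicate 3 (edgeR adjusted p = 0.0893, 0.157, 0.146 and 0.172), without control 2 and knockdown 2 (0.199), with the length and GC trend removed (0.0561) or with DESeq2 (0.0518).

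The tests of the genes near PTPRZ1, of the word ACACGA and its control words, and of the 8-base sites of GGAGAAA were chosen after the results were seen. The real grouping called 4243 genes and the highest of the other 9 splits 2; the real split was the 1 of 10 with as many, and 10 splits are too few for a share under 0.05.

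PTPRZ1 had 0 counts in the controls as well as in the knockdown. Loss of its reads to other genes of GENCODE 29 is argued against. Only 0.13% of the 31-base words of its transcripts occur in transcripts of those genes, and their exons overlap 0% of its exon bases. Genes that are only in the Ensembl annotation used for counting were not examined, so loss of reads to these stays open. A wide stretch left uncounted, as on chromosome 6, is argued against, since 5 of 10 protein-coding genes within 1 Mb (50%) had under 100 counts against 94.5% there (2-sided Fisher's exact test, p = 0.000292). Loss of its reads to alternate contigs or to copies that are not annotated, or in a stretch that holds no other gene, stays open, since no genome sequence was at hand to examine them. It also stays open that PTPRZ1 may be expressed below 0.0607 CPM in these A498 cells, which was not tested in other data.

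With no PTPRZ1 count before the knockdown, what the 4243 changed genes follow from is open. A trend with transcript length and GC content is argued against as the whole cause, since 95.5% of the calls remained with it removed. A seed match of the siRNA is not decided: the most negative word in 3' untranslated regions, GGAGAAA, reached an adjusted z of -6.47, but AGGAGAA (-5.76) and TGGAGAA (-5.08) lay close to it, it occurs in PTPRZ1 as 38.9% of the tested 7-base words do, the 1020 genes with AGGAGAAA differed in median log2 fold change by -0.0066 from genes without GGAGAA (2-sided permutation p = 0.37), and the siRNA's sequence is not given in the sources used here. As a description only, in the genes that picked the word, GGAGAA occurred in 52.3% of those called lower and in 47.9% of the others. A plasmid in 1 group and siRNA in the other, as the labels read, cannot be separated from the knockdown in this design and was not tested. Effects of the knockdown itself stay open as well.

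Some of the genes higher in the knockdown shared a sequence word. In the 3' untranslated region, ACACGAA had an adjusted z of 11.05 and AACACGA of 9.04. AACTCGA, the highest word that shares no 4 bases in a row with AACACGAA, reached 6.05. The largest value was 2.98 for 10 other words of the same bases with 1 CG and 4.44 in 20 scans of permuted fold changes. Permuting breaks any link between fold changes and sequence composition, so 4.44 is no ceiling for the real scan, where AACTCGA also exceeded it. The medians by site come from the genes of the scan that picked the word, and so are a description only. The median log2 fold change was 0.23 (95% bootstrap interval 0.16 to 0.29) for 79 genes with AACACGAA. It was 0.20 and 0.15 for those with ACACGAA or AACACGA alone, 0.07 for ACACGA alone and -0.02 without it. Of the 79 genes, 40 were called higher, MAF (1.16) and NCS1 (1.05) the most, and 5 lower, KCNMB4 (-0.76) the most. The other genes with AACACGAA did not pass. In 596 genes with a 7-base form only upstream of that region, at sites the scan had not used although it held these genes as ones without the word, the median lay 0.10 above genes without the word (0.1044, 2-sided permutation p = 1e-05, the smallest that 100000 permutations can give), but without the order seen in that region, at 0.06 for AACACGAA, 0.10 for ACACGAA alone and 0.07 for AACACGA alone. That permutation took no account of sequence length, GC content or expression level. For the 10 other words of the same bases the upstream difference was at most 0.0333, against 0.1119 for ACACGAA. A candidate explanation is a small RNA in the cells labelled control that lowered transcripts with ACACGA, and it could account for only a part of the calls. AACACGAA occurs in PTPRZ1, as 13.1% of all 8-base words do. Exchanged group labels, a control sequence with this seed and a biological source therefore cannot be ranked here. Exchanged labels would reverse all directions printed for this comparison, such as the fall of EGR1 and the rise of NRF2 targets.

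Among pairs of libraries within a group, the median ratio of observed to counting variance was taken for genes with 3000 or more summed counts. It was lowest between knockdown replicates 1 and 3 (2.29) and highest between control replicates 2 and 3 (11.58). The within-group ratios of the 2 groups overlap, with 4.33 between controls 1 and 3 and 4.18 between knockdown 2 and 3. The 2 highest within-group pairs both hold control 2 (8.98 with control 1). Pairs of a control and a knockdown library lay higher, from 25.5 to 37.95.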
